A study of Drosophila melanogaster with 6 samples.

How the data were processed

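RNA sequencing libraries from adult male Drosophila melanogaster were compared between 2 groups, 3 libraries of control flies and 3 libraries of flies overexpressing the long non-coding RNA CR46018, all collected 12 h after injection of the Gram-positive bacterium Micrococcus luteus. Per the labels, the control flies carried a temperature-sensitive Gal80 and a Tub-Gal4 driver over an attP40 landing site, and the other flies carried the same Gal80 with CR46018 under the Tub driver. The labels do not say whether the libraries of a group came from separate batches of flies, so p-values measure the spread between these libraries, part of which may be technical.

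Per the labels' protocols, the authors selected polyadenylated RNA, sequenced it in paired ends, aligned the reads with HISAT2 2.0.5 and counted them per gene with featureCounts 1.5.0-p3, and they tested differential expression with DESeq2. Per the submitters' processing notes the genome build was dm6. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The deposited values are FPKM, fragments per kilobase of gene scaled by library size, as the deposited table is named, with 1 column per library and no pooling of replicates. How the authors converted counts to FPKM is not given in the sources used here.

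The deposited FPKM table held 17558 genes, of which 15952 were above 0 in at least 1 library. Multiplied by the exonic length of the gene in the Ensembl annotation of the same genome assembly, the FPKM values of 97.7% of the genes above 0 with a known length fell on whole reads in all 6 libraries, within a tolerance of 0.01 reads. The recovered reads came to 17499997, 17553098 and 15631568 in control replicates 1 to 3 and to 18031741, 17233057 and 16552996 in overexpression replicates 1 to 3. The scaling of the deposited FPKM followed median-of-ratios factors within 0.64% and the recovered totals within 3.3%. A value of 0 therefore stands for 0 counted reads, and 0 of the 82 ribosomal protein genes was at 0 in any library. Where a group of 3 libraries had 0 reads, a floor of 3 reads over the group was used to give a lower bound of the fold difference. Such bounds and intervals cover counting error only.

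Of the gene identifiers, 17252 matched a current symbol and 306 did not. Of these, 153 were named by their exonic length, inferred from whole reads in genes with at least 100 reads: 150 matched a single current gene, and 3, Drosomycin (Drs, 387 bp), bor (2457 bp) and prg (2149 bp), matched 2 current genes, of which the only protein-coding one was taken. The identity of a gene named this way rests on its length.

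Replicates were first compared for duplicates. Over genes with a mean of at least 50 recovered reads, the chi-square per degree of freedom between replicates of a group ranged from 6.73 to 9.81, far above the value of 1 for sampling noise, so all 6 libraries were treated as distinct. Genes with a mean FPKM of at least 1 over the 6 libraries, 12251 in all, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The level of CR46018 was also compared with an exact two-sided permutation test of the 6 values, whose smallest p is 0.1.

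Gene lists were fixed before the data were examined: 30 lists of immune pathways and effectors, stress, detoxification and metabolic genes, cell type markers and transgene markers. The 29 lists with at least 3 tested members were tested with limma camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. The text names CR46018, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, up to 3 members with the smallest p of each list past an adjusted camera p of 0.05, up to 2 of any other list with a member past the threshold, and 16 immune genes fixed in advance: Drs, Mtk, Def, BomS1, BomS2, Dso1, Dif, dl, cact, spz, Tl, PGRP-SA, DptA, AttA, TotA and TotM. Other genes named in the text were chosen after their values were seen.

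The procedure was tested on simulated data drawn from the real means and read totals. Of 40 simulated genes per fold size, it recovered 82.5% at a fold of 1.5, 97.5% at 2 and 100% at 4, and called 9 of 11808 unchanged genes. Of 40 genes simulated lower, it recovered 85% at a fold of 0.667 and 97.5% at 0.5. Each simulated gene had the median spread of genes of like abundance, and no changed gene was at the lowest levels. Libraries were scaled by their known totals. The simulation therefore does not cover genes with a larger spread or an error in scaling.

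The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, rescaling to a common FPKM total per library (the TPM scale), median-of-ratios factors, quantile normalization, eBayes without trend or robust, array weights, the replicate number as a block, leaving out each library and an absolute log2 fold change of at least 1. Alternatives chosen after seeing the data were limma voom on the recovered reads with their totals as library sizes, leaving out X-linked genes, leaving out mitochondrially encoded genes before rescaling, and 3 added gene lists. Read positions within genes, splice junctions and the transgene sequence were not analysed here.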

Results

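Gene expression was measured by RNA sequencing of adult male flies 12 h after injection of Micrococcus luteus, a Gram-positive bacterium that activates the Toll pathway. The study compared 3 libraries from control flies with 3 libraries from flies that overexpressed the long non-coding RNA CR46018 under the tubulin driver, which is active in most tissues. By its title, the study asked about the Toll response and the NF-kappaB factors Dif and Dorsal. All libraries came from infected flies, so no uninfected level stands beside these values. Recovered reads ran from 15631568 to 18031741 per library. On the first principal component, which held 51.4% of the variance of log2(FPKM + 1), the control libraries lay between -16.79 and -12.16 and the overexpression libraries between 13.36 and 17.4. Pearson correlations across genes, which are not independent replicates, were between 0.9921 and 0.9929 within groups and between 0.9823 and 0.9872 across groups.

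CR46018 itself was barely counted in any library. CR46018 (asRNA:CR46018, FBgn0267682) is annotated in dm6 on chromosome 3R from 12634192 to 12634744 on the minus strand, with an exonic length of 553 bp. It had 0 reads in each of the 3 control libraries and 3, 1 and 0 reads in overexpression replicates 1, 2 and 3, which is 0.264, 0.0902 and 0 FPKM. A count of 0 in the control group allows a level of up to 0.0971 FPKM. The exact two-sided permutation test of log2(FPKM + 1) gave p = 0.4, and the smallest p that 3 against 3 libraries allow is 0.1. Of its 553 bp, 429 bp lie inside an exon of CG18530 (FBgn0042207), annotated on the plus strand from 12633359 to 12634670. The other 124 bp lie outside exons of the other strand. The strand setting of the counting is not given in the sources used here. How far the low count measures the expression of the transgene is therefore not known, and weak expression stays open. CG18530 measured 2.51 ± 0.573 FPKM in controls and 3.5 ± 1.11 FPKM in overexpressing flies (SD, n = 3; limma adjusted p = 0.326).

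In flies overexpressing CR46018, 300 genes were higher and 773 were lower than in controls among 12251 tested (limma, adjusted p under 0.05). Of these, 39 of the higher and 74 of the lower genes changed by at least 1 on the log2 scale. The groups did not overlap in 28.4% of tested genes, against 10% by chance for 3 against 3. The balance of the directions depended on scaling: with FPKM rescaled to a common total per library, 796 genes were higher and 479 lower, so that 62.4% of the calls were higher against 28% as deposited. Counts fell to 164 and 458 without control replicate 1, to 156 and 442 without control replicate 2, and to 135 and 428 without overexpression replicate 3.

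Several of the largest rises were genes with 0 reads in all 3 control libraries. CG14419 (FBgn0029639, X, 2885186 to 2885914) measured 15.5 ± 2.91 FPKM in overexpressing flies (SD, n = 3), at least 210-fold higher than the floor of 3 reads over the control group. CG12498 measured 9.24 ± 2.67 FPKM, at least 166-fold higher. CG3588 reached 5.01 ± 0.891 FPKM, at least 321-fold higher, and CG3526 reached 3.7 ± 1.46 FPKM, at least 82.8-fold higher. These 4 genes lie on the X chromosome between 2809881 and 2924426. The non-coding RNA lncRNA:CR44534, also X-linked at 9314685 to 9315171, was at 4.17 ± 1.12 FPKM, at least 37.9-fold higher. All 5 passed the threshold, with adjusted p from 9.76e-06 to 0.00122 (limma). The design does not separate overexpression from a different genetic background of the groups, for these genes or for any other difference reported here.

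**Figure D1:**
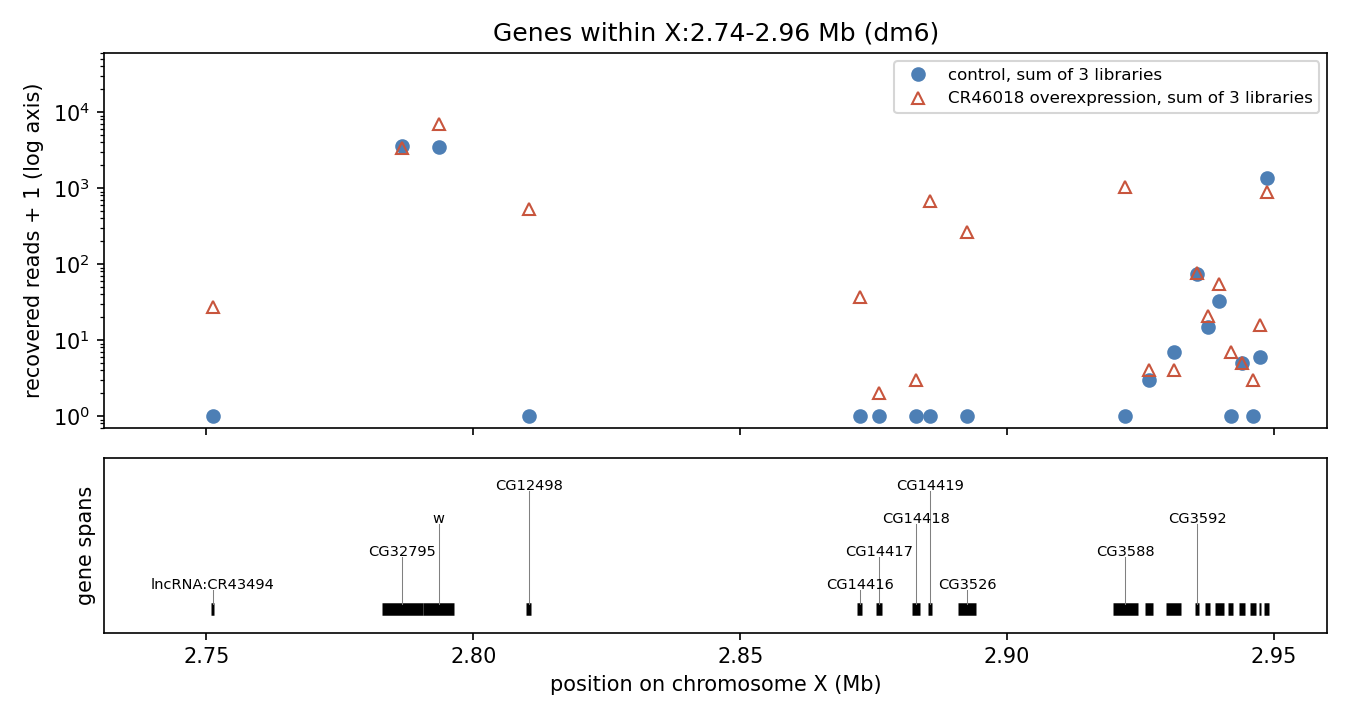
Recovered reads plus 1 on a log axis, summed over 3 libraries per group, of genes along part of the X chromosome in Mb, with circles for control and triangles for CR46018 overexpression and black bars below for gene spans. The genes drawn from CG12498 to CG3588 had 0 reads in the control libraries, while w before them had 3441. Many fly constructs carry w, so its reads may come from elsewhere. CG32795, next before w, had 3598 control reads. After CG3588, CG14424 and CG32793 had 2 and 6 control reads and 3 overexpression reads each. CG3592, next, had 72 control reads, so the second edge is not sharp.

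Other large rises were those of Hsp70Bb, CG30287, Cnx14D, CecA2 and CG33666. Hsp70Bb, a heat-inducible chaperone gene, rose from 3.17 ± 0.883 to 22.3 ± 1.44 FPKM (log2 fold change 2.51 ± 0.15 SE, n = 3, limma adjusted p = 0.000288). It has near-identical copies, so its own share of the reads is uncertain. The copies Hsp70Bc (log2 fold change -0.11, limma adjusted p = 0.795) and Hsp70Bbb (-0.06, adjusted p = 0.887) did not rise with it. The transgene sequence was not analysed, so where the added Hsp70Bb reads came from was not tested. CG30287 rose by 2.30 ± 0.15 (adjusted p = 0.000375), Cnx14D, a calnexin gene, by 1.95 ± 0.12 (adjusted p = 0.00033) and CG33666 by 1.85 ± 0.20 (adjusted p = 0.00187). With a pseudocount of 5 these 3 log2 fold changes were 1.19, 0.73 and 0.71.

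The largest fall was that of Jhbp4, with 506 recovered reads in controls and 2 in overexpressing flies. The control level was 270 times the overexpression level (95% counting interval 74.4 to 2240). Both reads were in overexpression replicate 3, so without that library the group has 0 reads and the ratio has only a lower bound. CG7203 fell from 175.6 ± 57.8 to 24.9 ± 3.4 FPKM (log2 fold change -2.73 ± 0.21 SE, limma adjusted p = 0.000696), and CG7214 fell from 39.5 ± 13.7 to 6.01 ± 0.889 FPKM. HSPBAP1 (-2.26 ± 0.44), Acp1 (-2.23 ± 0.24), Cpr62Bc (-2.02 ± 0.22), CG34327 (-1.98 ± 0.13), CG8736 (-1.97 ± 0.34), Obp99b (-1.93 ± 0.31) and lncRNA:CR45119 (-1.92 ± 0.18) followed, with adjusted p from 0.000375 to 0.0181 (limma). Cpr62Bc is named for a cuticle protein and Obp99b for an odorant-binding protein. Acp1, CG7214 and CG7203 lie close together on 2L, between 7740562 and 7753186. HSPBAP1 lost its call without control replicate 3 (adjusted p = 0.0511), overexpression replicate 1 (adjusted p = 0.057) or overexpression replicate 3 (adjusted p = 0.0643), in a range over 17 alternatives from 0.00339 to 0.0643. With a pseudocount of 5, the log2 fold change was -1.31 for Acp1, -0.79 for Cpr62Bc, -1.18 for CG34327, -1.01 for CG8736 and -0.84 for lncRNA:CR45119.

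Among the Bomanins, short secreted peptides induced by Toll, 0 of 12 members rose and 5 fell by limma, or 0 and 6 adjusted over the list alone. Voom called 1 higher and 5 lower. BomS6 fell from 386.7 ± 37.8 to 221 ± 34.9 FPKM (log2 fold change -0.81 ± 0.11 SE, n = 3, limma adjusted p = 0.00508), and BomT3 from 564 ± 46.3 to 364.9 ± 40.7 FPKM (-0.63 ± 0.09, adjusted p = 0.00695). BomBc2 (-0.38 ± 0.08), BomBc3 (-0.39 ± 0.10) and BomS2 (3438 ± 192 to 2539 ± 353 FPKM, adjusted p = 0.0352) were the other 3. BomS1 measured 6933 ± 347 and 6957 ± 684 FPKM (adjusted p = 0.995). The list median was -0.29 (camera adjusted p = 0.0114; adjusted p = 0.548 with an estimated correlation), and the list did not pass without control replicate 3 (adjusted p = 0.0689) or overexpression replicate 2 (adjusted p = 0.108), in a range over 19 alternatives from 0.00132 to 0.548. With quantile normalization the median was -0.185. BomS2 kept its call only without overexpression replicate 3 among the 6 fits that left out 1 library, with adjusted p up to 0.0998, and BomBc2 lost its call without control replicate 1 or 3 or overexpression replicate 2 or 3, with adjusted p up to 0.101.

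Other Toll effectors went both ways, with 2 of 12 members higher and 2 lower, or 3 and 3 adjusted over the list alone (median -0.011, mean 0.036, camera adjusted p = 0.87). With voom 4 were higher and 3 lower. The median turned positive with rescaling to a common total. Dso2 rose from 393 ± 45.5 to 648 ± 99.7 FPKM (log2 fold change 0.71 ± 0.13 SE, limma adjusted p = 0.0123), and BaraA1 from 167 ± 15.3 to 244 ± 33.9 FPKM (adjusted p = 0.0212). SPH93 fell from 57.6 ± 6.22 to 31.5 ± 3.01 FPKM (-0.85 ± 0.09, adjusted p = 0.00185), and SPE, the protease that cleaves Spätzle, fell by 0.26 on the log2 scale (adjusted p = 0.049). Drosomycin (Drs), the antifungal peptide commonly read as a marker of Toll output, measured 18111 ± 325 FPKM in controls and 17656 ± 1197 FPKM in overexpressing flies (-0.04 ± 0.08, adjusted p = 0.84), a difference that turned positive with rescaling. Its identifier was matched to its name by gene length. Metchnikowin (Mtk) measured 9111 ± 462 and 7422 ± 539 FPKM (adjusted p = 0.0665) and passed without overexpression replicate 1 (adjusted p = 0.035; range over 17 alternatives 0.035 to 0.599). Dso1 measured 1308 ± 129 and 1194 ± 147 FPKM (adjusted p = 0.504). In the list named Drosomycin family, 1 of 5 members passed, also adjusted over the list alone, namely Drsl3, which rose from 8.55 ± 1.53 to 20.1 ± 4.95 FPKM (adjusted p = 0.0089; list median 0.24, camera adjusted p = 0.111). That list passed without the filter on low values (adjusted p = 0.0471) and with the replicate number as a block (adjusted p = 0.0352), in a range over 19 alternatives from 0.0352 to 0.421.

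**Figure D2:**
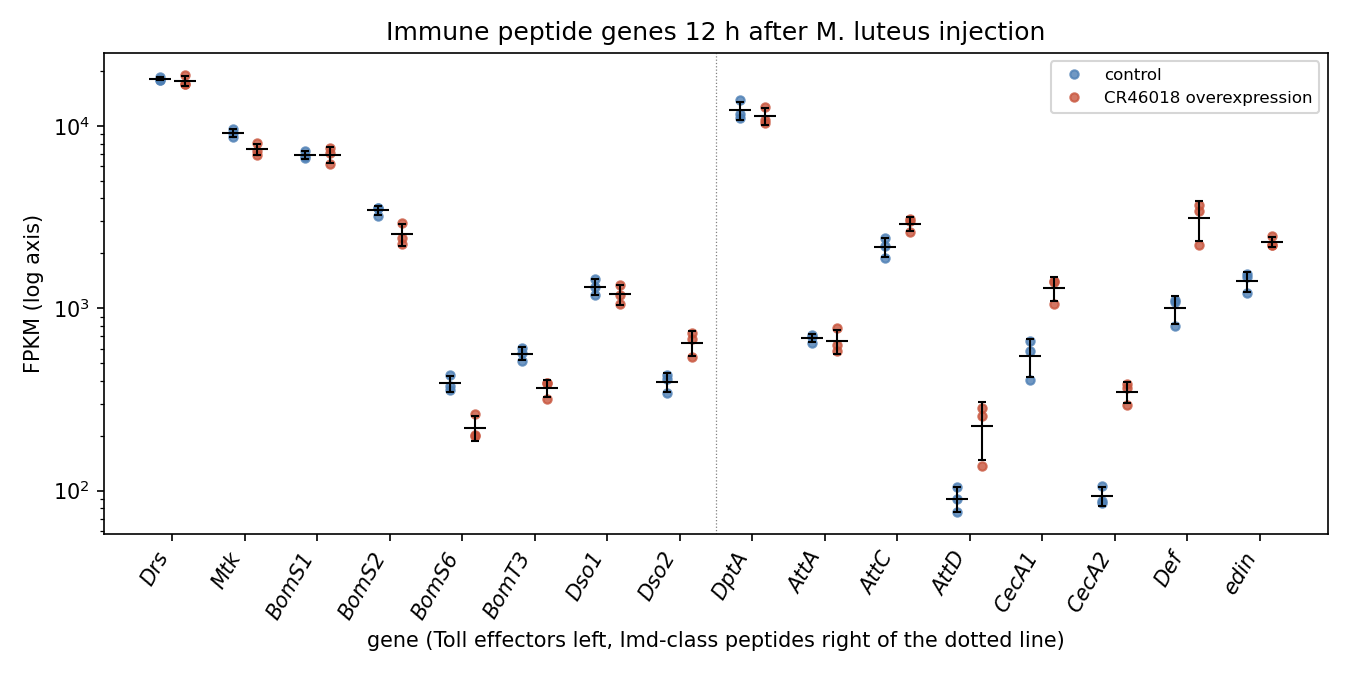
FPKM on a log axis of 8 Toll effector genes and 8 Imd-class peptide genes in each library, with control libraries in blue, CR46018 overexpression in red, and black bars for the mean and SD of 3 libraries. Drs, BomS1 and DptA overlap between the groups, BomS6 and BomT3 lie lower and CecA2, Def and edin higher in the overexpression libraries.

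Of 27 tested Toll pathway components, 1 rose and 5 fell by limma, the same counts as adjusted over the list alone. With voom 3 were higher and 5 lower. The protease gene psh fell from 13.1 ± 0.305 to 8.45 ± 0.19 FPKM (log2 fold change -0.58 ± 0.06 SE, n = 3, limma adjusted p = 0.00131), and the glucan sensor GNBP3 from 48.4 ± 2.2 to 35.8 ± 1.71 FPKM (adjusted p = 0.00474). The others were modSP, 18w and SPE, which fell, and spirit, which rose. The fall of SPE is also counted among the other Toll effectors. The NF-kappaB genes did not pass: Dif measured 22.5 ± 0.953 and 20.5 ± 1.1 FPKM (adjusted p = 0.245), and dl 15.8 ± 0.494 and 13.7 ± 0.912 FPKM (adjusted p = 0.117). The inhibitor gene cact measured 57.7 ± 2 and 66.6 ± 14.5 FPKM, spz 21.7 ± 1.43 and 24 ± 4.46 FPKM, Tl 12.3 ± 0.627 and 11.5 ± 1.37 FPKM and the receptor gene PGRP-SA 94.5 ± 4.86 and 101.2 ± 0.542 FPKM, with adjusted p from 0.308 to 0.61. Without overexpression replicate 2, cact passed (log2 fold change 0.36, adjusted p = 0.033; range over 17 alternatives 0.033 to 0.902). The list did not pass (median -0.04, camera adjusted p = 0.256), and its median turned positive with rescaling to a common total.

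The list of Imd-class peptides, named for the other humoral arm of fly immunity, had 6 of 15 members higher and 0 lower by limma. Adjusted over the list alone, 9 were higher and 0 lower. The list also holds PGRP-SB1 and PGRP-SD, which are not antimicrobial peptide genes. PGRP-SD is also among the Toll pathway components. With or without PGRP-SD, the list does not separate Imd from Toll, since no library here had either pathway blocked. CecA2, a cecropin gene, rose from 93.3 ± 11.2 to 347.8 ± 47.2 FPKM (log2 fold change 1.88 ± 0.12 SE, n = 3, limma adjusted p = 0.000288). Defensin (Def), active against Gram-positive bacteria, rose from 996 ± 174 to 3104 ± 776 FPKM (1.62 ± 0.20, adjusted p = 0.00302), and edin from 1409 ± 179 to 2314 ± 157 FPKM (0.72 ± 0.10, adjusted p = 0.00492). The other 3 were CecA1 (1.24 ± 0.18), AttD (1.26 ± 0.25) and AttC (0.43 ± 0.10). DptA, a diptericin gene, measured 12162 ± 1437 and 11276 ± 1211 FPKM (adjusted p = 0.636), and the attacin gene AttA 686 ± 36.4 and 660.6 ± 102 FPKM (adjusted p = 0.774), and both differences turned positive with quantile normalization. DptB (-0.08 ± 0.09, adjusted p = 0.642) and Dro (-0.15 ± 0.10, adjusted p = 0.413) did not pass either. The list median was 0.43, the value of PGRP-SD (camera adjusted p = 2.45e-05; adjusted p = 0.414 with an estimated correlation). CecA1 and CecA2, like AttA and AttB, are close copies, so their reads may be divided between them.

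Among 20 Imd pathway components, 4 rose and 0 fell by limma, or 11 and 0 adjusted over the list alone (median 0.22, camera adjusted p = 5.56e-07; adjusted p = 0.302 with an estimated correlation). PGRP-SC1a rose from 1.45 ± 0.265 to 3.49 ± 0.627 FPKM, PGRP-SC1b from 2.59 ± 0.38 to 4.92 ± 0.858 FPKM and the caspase inhibitor gene Diap2 from 76.1 ± 1.58 to 92.4 ± 3.27 FPKM, with adjusted p from 0.00771 to 0.0139 (limma), and the other was pirk. PGRP-SC1a and PGRP-SC1b encode amidases that dampen the Imd response, as pirk does, and are near-identical copies. With a pseudocount of 5 the log2 fold change was 0.39 for PGRP-SC1a and 0.38 for PGRP-SC1b. PGRP-SC1b lost its call without control replicate 2 (adjusted p = 0.0501; range over 16 alternatives 0.00898 to 0.0501) and Diap2 without control replicate 1 (adjusted p = 0.0573; range over 17 alternatives 0.00591 to 0.0573).

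The stress gene TotA measured 161.8 ± 70 and 83.5 ± 13 FPKM (limma adjusted p = 0.123), and TotM 9.11 ± 2.09 and 11.2 ± 2.61 FPKM (adjusted p = 0.418). Without control replicate 3, TotA passed (log2 fold change -1.23, adjusted p = 0.0102; range over 17 alternatives 0.0102 to 0.281). Of 13 JAK/STAT and Turandot genes 0 passed by limma, also adjusted over the list alone, with 5 at an unadjusted p under 0.05 and 3 called by voom, 2 higher and 1 lower (median 0.063, mean -0.027, camera adjusted p = 0.805). Among 16 melanization and clotting genes, 2 rose and 2 fell, or 4 and 4 adjusted over the list alone (median -0.026, mean 0.10, camera adjusted p = 0.813). Ddc, the dopa decarboxylase gene, rose from 24.9 ± 5.09 to 95.4 ± 45.8 FPKM (adjusted p = 0.00851), and Spn28Dc rose, while yellow-f2 fell by 0.53 on the log2 scale (adjusted p = 0.00855) and Lsp1gamma also fell. Of 13 heat shock and chaperone genes, Hsp70Bb rose and DnaJ-1 fell from 122.6 ± 14.1 to 87.8 ± 3.64 FPKM (adjusted p = 0.0135), also when adjusted over the list alone (median 0.035, camera adjusted p = 0.568). DnaJ-1 lost its call without control replicate 2 (adjusted p = 0.0518; range over 17 alternatives 0.00699 to 0.0518). Of 15 JNK and wound genes, Gadd45 alone passed, rising from 23.5 ± 0.165 to 34.7 ± 4.12 FPKM (adjusted p = 0.00784), with 3 higher adjusted over the list alone (median 0.024, camera adjusted p = 0.256).

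Of 32 glutathione transferases, 0 rose and 12 fell by limma, or 2 and 14 adjusted over the list alone (median -0.17, camera adjusted p = 2.45e-05; adjusted p = 0.199 with an estimated correlation). GstE7 fell from 39.6 ± 4.83 to 21.3 ± 2.52 FPKM (limma adjusted p = 0.00325), with smaller falls of GstE1 (-0.41 ± 0.06) and GstE3 (-0.44 ± 0.07). Of 72 cytochrome P450 genes, 2 rose and 15 fell, or 4 and 21 adjusted over the list alone (median -0.16, camera adjusted p = 3.88e-05; adjusted p = 0.302 with an estimated correlation). Cyp309a1 fell from 20.5 ± 1.78 to 9.42 ± 1.04 FPKM (adjusted p = 0.000978), Cyp4d20 (-0.93 ± 0.09) and Cyp6g1 (-0.55 ± 0.07) also fell, and those that rose were Cyp6a8 and Cyp4p3. With FPKM rescaled to a common total, the medians were closer to 0, at -0.076 for Glutathione transferases and -0.061 for Cytochrome P450 genes, and both lists passed camera. The P450 median was -0.1 with a pseudocount of 5. Fat body (median -0.75), hemocyte (-0.56) and muscle markers (-0.42) fell too. Whether a smaller share of these tissues underlies the falls of both detoxification lists was not tested.

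Of 17 genes of lipid synthesis and storage, 0 rose and 10 fell by limma, or 0 and 12 adjusted over the list alone (median -0.29, camera adjusted p = 5.28e-07; adjusted p = 0.302 with an estimated correlation). The fatty acid synthase gene FASN1 fell from 128 ± 17.8 to 67.2 ± 5.59 FPKM (limma adjusted p = 0.00191), the acyltransferase gene mdy from 11.5 ± 0.362 to 6.75 ± 0.524 FPKM (adjusted p = 0.00153) and ACC, the acetyl-CoA carboxylase gene, from 74.7 ± 5.27 to 48.7 ± 4.47 FPKM (adjusted p = 0.00415). Of 14 glycolysis genes, 0 rose and 6 fell, or 0 and 10 adjusted over the list alone (median -0.21, camera adjusted p = 1.37e-05; adjusted p = 0.392 with an estimated correlation). Pglym78 fell from 210.6 ± 15.2 to 136.7 ± 5.53 FPKM (adjusted p = 0.00169), and Pgk (-0.54 ± 0.07) and Gpdh1 (-0.42 ± 0.05) also fell. Of 84 nuclear genes of oxidative phosphorylation, 3 rose and 27 fell, or 7 and 46 adjusted over the list alone (median -0.18, camera adjusted p = 4.1e-07; adjusted p = 0.414 with an estimated correlation). ND-B15 (-0.41 ± 0.05), ND-B18 (-0.37 ± 0.05) and ND-15 (-0.43 ± 0.06), which encode complex I subunits, had adjusted p from 0.00249 to 0.00388, and those that rose were ATPsynCF6L, ND-24L and ND-51L1. With rescaling to a common total, the median was -0.11 for Glycolysis and -0.082 for Oxidative phosphorylation, with quantile normalization it was -0.093 and -0.092, and both lists passed camera each time. The medians of muscle markers (-0.42), fat body markers (-0.75) and mitochondrially encoded genes (-0.56) were also below 0, and whether the lipid, glycolysis and oxidative phosphorylation falls come from a smaller share of these tissues was not tested. Of 12 insulin and FoxO genes, 2 rose and 0 fell by limma, or 3 and 0 adjusted over the list alone (median -0.041, mean 0.054, camera adjusted p = 0.57), with 4 at an unadjusted p under 0.05 and 3 higher by voom. They were ImpL2, a secreted insulin antagonist (71.7 ± 2.62 to 104 ± 11.5 FPKM, adjusted p = 0.00784), and Thor, the translation repressor 4E-BP (316 ± 25.3 to 472 ± 60.3 FPKM, adjusted p = 0.0117).

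Of 10 fat body markers, 0 rose and 5 fell by limma, or 0 and 6 adjusted over the list alone (median -0.75, camera adjusted p = 1.37e-05; adjusted p = 0.376 with an estimated correlation), and without control replicate 1 the median was -0.42. The 5 were FASN1 and Lsd-1, also counted among the lipid genes, Sid, Obp99b and the lipophorin gene apolpp (106.4 ± 20.5 to 31.7 ± 11.1 FPKM, adjusted p = 0.00478). The fat body is a main source of immune peptides. Of 12 hemocyte markers, 0 rose and 6 fell, or 0 and 8 adjusted over the list alone (median -0.56, camera adjusted p = 1.24e-06; adjusted p = 0.376 with an estimated correlation). The collagen IV genes Col4a1 (37.1 ± 3.08 to 17.2 ± 2.73 FPKM) and vkg (24.6 ± 1.4 to 12 ± 1.86 FPKM), which fat body also expresses, and the phagocytosis receptor gene NimC1 (4.93 ± 0.198 to 2.32 ± 0.251 FPKM) each had adjusted p = 0.00172. The median of Hemocyte markers was -0.365 with a pseudocount of 5 and -0.33 without the filter on low values, and NimC1 was at -0.44 with that pseudocount. Of 17 muscle markers, 0 rose and 9 fell, or 0 and 14 adjusted over the list alone (median -0.42, camera adjusted p = 6.88e-08; adjusted p = 0.392 with an estimated correlation), with TpnC41C (-0.74 ± 0.11), Mlc2 (-0.69 ± 0.10) and TpnC4 (-0.57 ± 0.09).

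**Figure D3:**
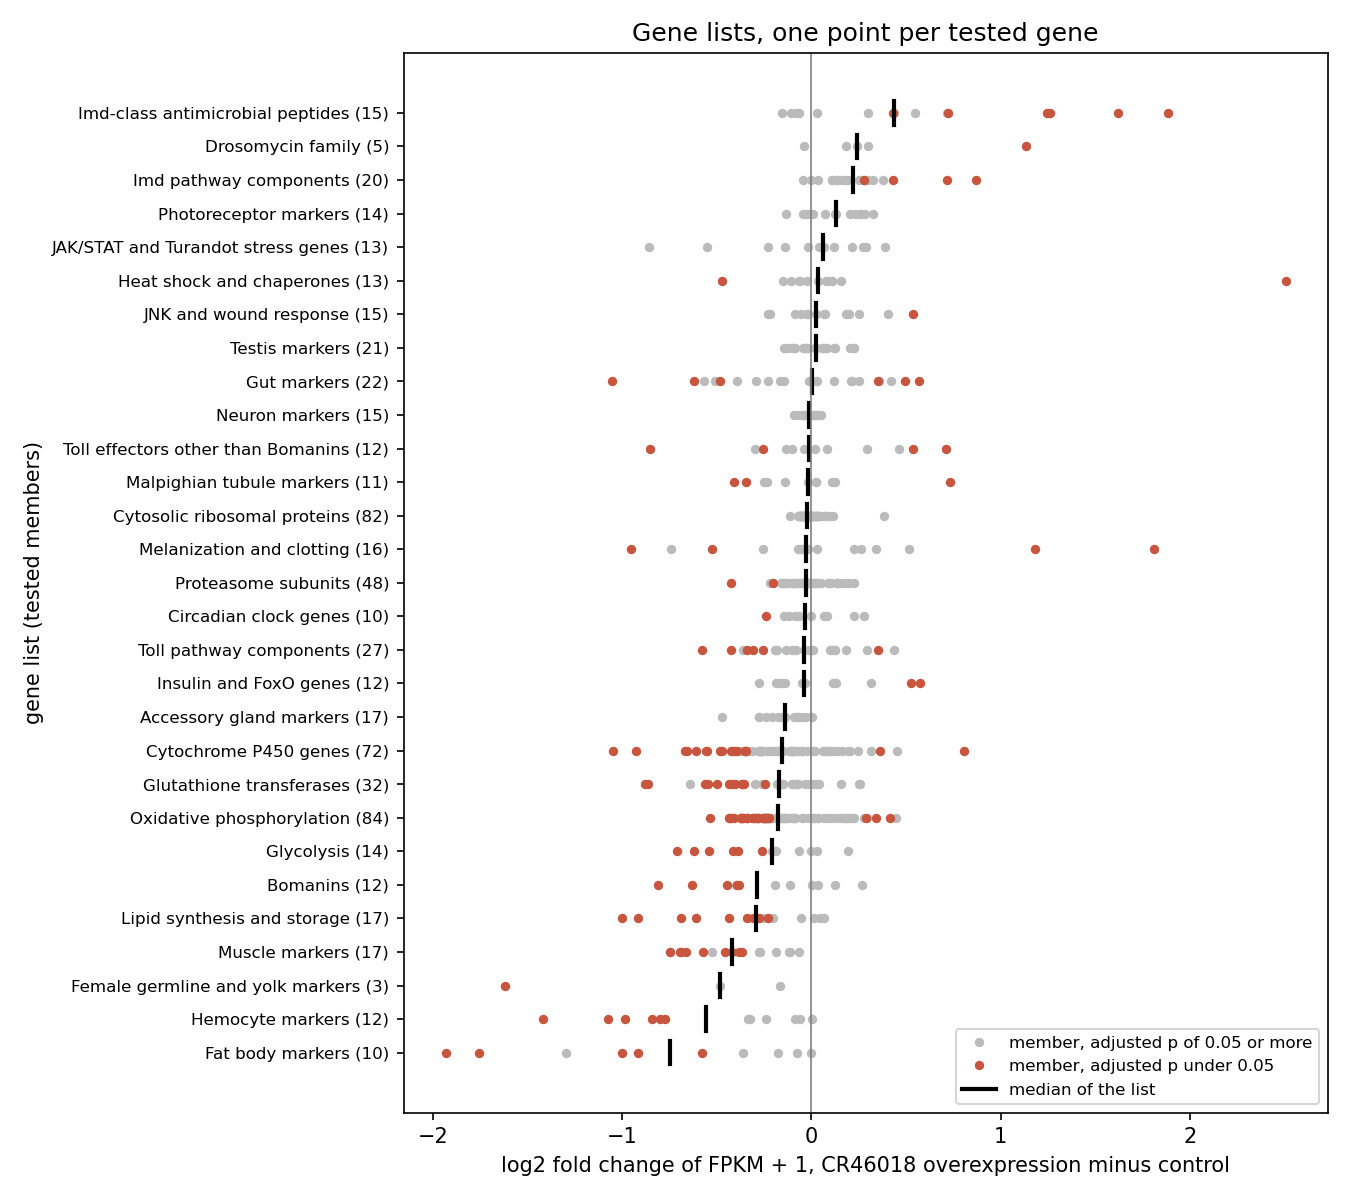
Log2 fold change of FPKM + 1, CR46018 overexpression minus control, of every tested member of 29 gene lists, with red points for genes at an adjusted p under 0.05, grey points for the others and black lines for list medians. Medians run from -0.75 in fat body markers to 0.43 in Imd-class peptides, and some of those near 0 turn sign with rescaling to a common total.

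Yp3, a yolk protein gene, fell from 32.4 ± 1.04 to 10 ± 2.19 FPKM (limma adjusted p = 0.000747) and was the 1 call of 3 tested female germline and yolk markers, also when adjusted over the list alone (median -0.48, camera adjusted p = 0.0161; adjusted p = 0.376 with an estimated correlation). Cp18 measured 3.04 ± 0.645 and 1.96 ± 0.962 FPKM, with adjusted p = 0.24, and passed without overexpression replicate 3 (adjusted p = 0.0471; range over 16 alternatives 0.0471 to 0.48), where the list median was -0.73. The median of Female germline and yolk markers was -0.213 with a pseudocount of 5 and -0.047 without the filter on low values, where the list did not pass (adjusted p = 0.278; range over 18 alternatives 0.00199 to 0.376). Cp15 measured 3.6 ± 0.495 and 3.1 ± 0.332 FPKM. Of 17 accessory gland markers 0 passed by limma, also adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 0 of 16 tested by voom (median -0.14, camera adjusted p = 0.0161; adjusted p = 0.744 with an estimated correlation). Acp63F measured 345 ± 30.9 and 284.7 ± 20.2 FPKM, Acp98AB 51.7 ± 11.6 and 36.3 ± 0.665 FPKM and SP, the sex peptide gene, 256.7 ± 30.5 and 211 ± 14.6 FPKM. Without control replicate 1, Acp98AB (adjusted p = 0.0122; range over 17 alternatives 0.0122 to 0.175) and SP (adjusted p = 0.0414; range 0.0414 to 0.302) passed. Accessory gland markers as a list did not pass without control replicate 1 (adjusted p = 0.0629) or 3 (adjusted p = 0.0753) or overexpression replicate 1 (adjusted p = 0.0619) or 3 (adjusted p = 0.115), in a range over 19 alternatives from 7.24e-05 to 0.744. Its median was -0.042 with rescaling to a common total and -0.04 with quantile normalization, where it did not pass (adjusted p = 0.417).

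Of 14 photoreceptor markers 0 passed by limma, also adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 5 of 12 tested higher by voom (median 0.13, camera adjusted p = 0.0283; adjusted p = 0.844 with an estimated correlation). Rh3, a rhodopsin gene, measured 50 ± 2.92 and 58.8 ± 3.82 FPKM, Rh6 28.5 ± 1.33 and 36.2 ± 5.43 FPKM and Arr1, an arrestin gene, 310.9 ± 14.7 and 380.6 ± 47.6 FPKM. Without overexpression replicate 2, Rh6 (adjusted p = 0.0105; range over 17 alternatives 0.0105 to 0.267) and Arr1 (adjusted p = 0.0137; range 0.0137 to 0.293) passed and the list median was 0.24. Photoreceptor markers as a list did not pass without control replicate 1 (adjusted p = 0.0725) or 3 (adjusted p = 0.0689) or overexpression replicate 1 (median 0.08, adjusted p = 0.236) or 3 (median 0.065, adjusted p = 0.17), in a range over 19 alternatives from 6.49e-07 to 0.844. With rescaling to a common total its median was 0.224.

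Of 22 gut markers, 3 rose and 3 fell, or 6 and 4 adjusted over the list alone (median 0.003, mean -0.065, camera adjusted p = 0.87). The maltase genes Mal-A1 (279 ± 17.6 to 181 ± 11.4 FPKM) and Mal-A6 (207.7 ± 14.7 to 148.5 ± 10.6 FPKM) fell, as did the protease gene Jon99Fi, while the protease genes epsilonTry, betaTry and Jon74E rose. Of 11 Malpighian tubule markers, 1 rose and 2 fell, or 1 and 3 adjusted over the list alone (median -0.019, camera adjusted p = 0.581). Uro, the urate oxidase gene, rose from 45 ± 3.42 to 75.3 ± 2.67 FPKM (limma adjusted p = 0.000996), and NaPi-T (-0.41 ± 0.07) and Oatp58Db fell. The transgene marker white (w), carried by many fly constructs, rose from 26.2 ± 1.38 to 49.7 ± 6.14 FPKM (adjusted p = 0.00141) and was the 1 call of 2 tested transgene markers, also when adjusted over the list alone.

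Of 48 proteasome subunits, Prosalpha4 and Prosbeta7 fell (limma adjusted p = 0.00664 and 0.0385) and 0 rose, with 11 at an unadjusted p under 0.05, and 1 fell adjusted over the list alone (median -0.027, camera adjusted p = 0.375). Prosbeta7 lost its call in each fit without 1 library except that without overexpression replicate 1, with adjusted p up to 0.141, and with rescaling to a common total (log2 fold change -0.11, adjusted p = 0.179) or quantile normalization (-0.11, adjusted p = 0.233; range over 17 alternatives 0.0293 to 0.233). Of 10 clock genes tim alone passed, also adjusted over the list alone, falling from 29.1 ± 0.618 to 24.5 ± 0.901 FPKM (adjusted p = 0.0294; list median -0.034, camera adjusted p = 0.825), and it lost its call in each fit without 1 library except that without overexpression replicate 2, with adjusted p up to 0.112, and with rescaling (log2 fold change -0.15, adjusted p = 0.126; range over 17 alternatives 0.0215 to 0.126). Of 82 cytosolic ribosomal protein genes and 15 neuron markers, 0 passed by limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. By voom 0 passed of the 80 and 11 of them that it tested. Of 21 testis markers, 0 passed by limma in either way, with 4 at an unadjusted p under 0.05 and 2 higher by voom. The medians were -0.022 for ribosomal proteins, -0.011 for neurons and 0.023 for testis (camera adjusted p = 0.785, 0.87 and 0.568). Testis markers as a list passed with quantile normalization (median 0.08, adjusted p = 0.00228; range over 19 alternatives 0.00228 to 0.954). The medians of the melanization, insulin, Malpighian tubule, proteasome, clock, ribosomal and neuron lists turned positive with rescaling to a common total, where Cytosolic ribosomal proteins passed (median 0.074, adjusted p = 0.0118; range over 19 alternatives 1.64e-05 to 0.946).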

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

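Voom on recovered reads and the fits without X-linked or without mitochondrially encoded genes were chosen after seeing the data. Counts of 300 higher and 773 lower genes moved by over 1.5 times in these cases: 796 and 479 with rescaling to a common total, 456 higher with mitochondrially encoded genes left out before rescaling, 894 higher with voom (733 lower), and 39 and 74 with a log2 fold change of at least 1, by construction. Without 1 library they ran from 135 to 286 and from 428 to 628, with fewer samples. All 300 higher genes were among the 796 after rescaling, and 475 of the 773 lower genes were among the 479. The cause of the other moves was not tested. With the replicate number as a block, 219 were higher and 616 lower and 15 lists passed, but the numbers do not pair the libraries: deviations of same-numbered libraries correlated across genes at 0.046, -0.076 and 0.026, against highest values with another number of -0.006, 0.062 and 0.084.

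Of 14 lists past camera, 0 passed with an estimated correlation (4 lists at an unadjusted p under 0.05), 9 lists passed with fry, and 11 to 14 passed without 1 library. Those past fry were the Imd pathway, glutathione transferase, P450, oxidative phosphorylation, glycolysis, lipid, fat body, hemocyte and female germline lists. Muscle (fry adjusted p = 0.058), accessory gland (fry adjusted p = 0.287) and photoreceptor markers (fry adjusted p = 0.5) did not pass fry. The Bomanin median of -0.289 lost its call with an estimated correlation (adjusted p = 0.548) and fry (adjusted p = 0.146), and ran from -0.307 to -0.235 without 1 library. The Imd-class median of 0.435 lost its call with an estimated correlation (adjusted p = 0.414) and fry (adjusted p = 0.0653). The CR46018 difference never passed, in log2 values from 0.009 with quantile normalization to 0.93 with a pseudocount of 0.1. It has no value at a mean FPKM of at least 5. Fits of deposited counts were not run, since the table holds FPKM.

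Of 1565 alternative values of named genes, 1502 kept direction and side of the threshold, 37 lost the call, 16 gained it and 10 changed sign. Of 550 values of lists, 484 kept both, 31 lost the call, 4 gained it and 31 changed the sign of the median. None of the results that changed sign passed as deposited. The summed FPKM ran from 694593 to 708815 in control libraries and from 646862 to 668227 in overexpression libraries. Rescaling to a common total thus multiplied all genes of a library by 1 factor. The median log2 fold change of all tested genes moved from -0.002 as deposited to 0.085 with rescaling. The cause of the sign changes in other settings was not tested. With rescaling the values were 0.031 for AttA, 0.057 for Drs and for other Toll effectors, 0.043 for the Toll pathway, 0.058 for clock genes, 0.074 for ribosomal proteins and Malpighian tubules, 0.051 for insulin genes, 0.069 for melanization, 0.073 for neurons and 0.067 for the proteasome. With quantile normalization they were 0.045 for AttA, 0.105 for DptA, 0.037 for other Toll effectors, 0.071 for ribosomal proteins (adjusted p = 1.64e-05), 0.02 for melanization and 0.023 for the proteasome. Gut markers were at -0.002 with a pseudocount of 5, -0.015 at a mean FPKM of at least 5 and -0.085 with array weights, and at that filter JNK genes were at -0.019 and melanization at 0.103. Without 1 library, values ran from -0.186 to 0.022 for AttA, -0.059 to 0.081 for BomS1, -0.149 to 0.002 for Tl, -0.062 to 0.02 for other Toll effectors, -0.054 to 0.004 for ribosomal proteins, -0.105 to 0.101 for gut, -0.04 to 0.083 for heat shock, -0.006 to 0.059 for JNK, -0.036 to 0.008 for melanization, -0.03 to 0.041 for neurons and -0.02 to 0.057 for testis.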

Other observations

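The overlap test, the 0.1 bound of the scaling test and the splits of the libraries were planned before their results were seen, and the other tests in this part, the 3 added gene lists and the test of the X chromosome were chosen afterwards. Cuticle genes, which encode structural proteins of the exoskeleton, had 0 of 41 members higher and 14 lower by limma (median -0.31, camera adjusted p = 3.7e-06; adjusted p = 0.251 with an estimated correlation). Besides Acp1 and Cpr62Bc, Cpr49Ab fell from 200.3 ± 6.29 to 120.7 ± 15.6 FPKM (SD, n = 3) and Cpr65Au from 254.7 ± 5.1 to 168.7 ± 20.4 FPKM. The medians of fat body (-0.75), hemocyte (-0.56) and muscle markers (-0.42) were also below 0. Whether the cuticle fall comes from a smaller share of some tissue was not tested. Of 13 protein-coding genes of the mitochondrial genome, 0 rose and 8 fell (median -0.56, camera adjusted p = 3.07e-08; adjusted p = 0.319 with an estimated correlation). mt:ND4 fell from 879.6 ± 14.4 to 438.9 ± 28 FPKM (limma adjusted p = 0.000288) and mt:ND5 from 1224 ± 44.8 to 643 ± 55 FPKM. Of 32 odorant-binding protein genes, 1 rose and 7 fell (median -0.075, camera adjusted p = 0.117). Hsp70Bb rose, while another copy, Hsp70Bc, measured 1.91 ± 0.817 and 1.64 ± 0.254 FPKM (limma adjusted p = 0.795).

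Calls of higher expression were more frequent on the X chromosome, with 78 of 1891 tested genes (4.1%) against 218 of 10263 autosomal genes (2.1%; odds ratio 1.98, two-sided Fisher's exact p = 1.31e-06, with genes not independent). For lower expression the shares were 6.9% and 6.1% (odds ratio 1.13, Fisher's exact p = 0.235). The X-linked eye colour gene vermilion, v, fell by 0.69 on the log2 scale (limma adjusted p = 0.00184).

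Over the 10 ways to split the 6 libraries 3 against 3, the real split gave 300 higher and 773 lower genes by limma, and the highest other split gave 0. In both directions 1 of the 10 splits, the real one, gave as many. For gene lists past the camera threshold the real split gave 14 and the highest other split 14, so 2 of the 10 gave as many. With 10 splits no share under 0.05 can be reached. Camera at the preset correlation thus called as many lists in a split that mixes the groups. Every other split mixes them, which leaves the group difference partly within and partly between its sides. That lowers the limma calls and can add camera calls, so the counts of the other splits do not measure false calls.

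CR46018 had only 4 reads in the overexpression libraries. CG18530, on the other strand, had 167 reads in controls and 249 in overexpressing flies, and the upper 95% limit of its log2 fold change was 0.78, so counting of some CR46018 fragments for CG18530 stays open. A candidate explanation is that fragments overlapping both genes were left uncounted: of 84 protein-coding genes at least 95% inside exons of the other strand, 91.7% had 0 reads in all libraries, against 4.6% of 10129 genes with none inside. Of 164 non-coding genes 75 to 95% inside, the range that holds CR46018, 46.3% had 0 reads, against 25.1% of 2884 with none inside, so whether overlap accounts for the whole shortfall stays open. A weakly transcribed transgene or a transcript with little polyadenylation was not tested and stays open.

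Of 10 genes with 0 reads in 1 group and at least 20 in the other, all 10 had their 0 in the controls and 9 are X-linked, the exception being AANATL6 on 2R. Sequencing depth was argued against, since counting noise alone, over the 13741 genes with at least 20 reads, is expected to give 0.000153 genes with 0 control reads and at least 20 in the other group, which covers counting error only. A single missing or silent stretch from lncRNA:CR43494 to CG3588 in the control background was argued against by CG32795, which lies inside it and had 3598 control reads. From CG12498 to CG3588 (X, 2809881 to 2924426) such a stretch cannot be told apart from an effect of CR46018, since 0 of the 2 other genes inside had at least 10 control reads and these had 1 and 2 reads in the overexpression libraries. The gene kirre runs through the whole stretch with 488 control and 802 overexpression reads, but only 53 of its 7853 exonic bp lie inside, so its reads do not decide, and a different genetic background of the groups, which the design does not separate from overexpression, stays open.

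By limma, 6 of 15 genes of the Imd-class list rose and 5 of 12 Bomanins fell. Both list calls were lost with an estimated correlation (adjusted p = 0.414 and 0.548) and with fry (adjusted p = 0.0653 and 0.146). A smaller share of fat body RNA, whose marker median was at most -0.418 in every fit without 1 library, stays open. A smaller share would lower peptides made there, so it could bear on the Bomanin fall. The Imd-class median went the other way, at least 0.384 in those fits, but these reuse the libraries in which the rise was seen. A single factor per library as the cause of the gap of 0.724 between the list medians was argued against, since such a factor cannot move it. Quantile normalization moved the gap by 0.096, under the bound of 0.1 set beforehand. The fits without 1 library alone spread the gap from 0.627 to 0.886, so the bound does not decide whether scaling has a part. The Bomanin median was -0.193 with rescaling and -0.185 with quantile normalization, and the Imd-class median 0.531 and 0.443. A criterion that both medians keep their direction by more than 1 SD over the fits without 1 library was met. It was added after these values were seen, and those fits share libraries, so it decides nothing. An effect of CR46018 and a difference in genetic background were not tested and stay open.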
